A study of Scomber scombrus with 32 samples.

How the data were processed

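The series holds 32 RNA libraries of the mackerel muscle lines Mack1 (24 libraries) and Mack2 (8), in 10 groups taken from the labels: 8 of Mack1 (p27 and p77, each in proliferation, serum starvation, serum reduction and lipid loading, 3 libraries each) and 2 of Mack2 (p2 and p180 in proliferation, 4 libraries each). Poly(A) libraries, not strand-specific, were read as 150 nt pairs, per the labels' protocols. The submitters' processing notes name FastQC, STAR, Salmon 1.10.1 and DESeq2 without saying what each was used for. The genome build, the annotation and how reads that fit several genes were handled are not given in the sources used here. The labels also give a batch, 1 for all Mack1 libraries and 2 for Mack2, except for Mack2 p2 replicate 4, which is labelled 1. Replicate 1 of Mack2 p180 has another cell type wording in its labels than the other 3 and was kept in its group.

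The first deposited table holds raw counts per gene, whole numbers for 24189 genes in each library, per the file name and the values; whether they are read counts or rounded estimates is not given in the sources used here. The second deposited table holds a normalized signal, and from its values it is the raw count divided by 1 size factor per library (0.6212 to 1.3431), which equals the median-of-ratios factor over all libraries. All gene numbers matched the RefSeq gene table of the assembly fScoSco1.1, which gave a symbol for 14498 of them and a locus number alone for 9691. Gene symbols, spans and chromosomes are from that table. Total counts ran from 16.9 to 32.01 M per library, and 2703 genes had no count anywhere. Ribosomal RNA genes held 0.4519 to 2.8497% of the counts. Between the 36 pairs of replicates, the chi-square per degree of freedom over genes with at least 10 counts was 3.25 to 84.1, so the spread exceeded counting error in each pair. CPM were computed from the raw counts with TMM-scaled totals.

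Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, a quasi-likelihood fit of group means (glmQLFit) and two-sided contrasts (glmQLFTest), with Benjamini-Hochberg adjustment over the genes tested in each contrast. A gene passed at an adjusted p under 0.05, and genes past it by at least 2-fold were counted too. One fit held all Mack1 libraries (15683 genes, common biological coefficient of variation 0.137), one the Mack2 libraries (13805 genes, 0.0575) and one the 14 proliferating libraries of both lines (14706 genes, 0.0735). They gave 17 comparisons set in advance, 4 of them differences of differences, and 2 added later, lipid loading against serum reduction at each Mack1 stage. Levels were not compared across lines, since line and batch nearly coincide. A fold against a group with no count is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio of total counts is given with its 95% counting interval.

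In advance 32 gene lists were written from general knowledge and matched by symbol, fish duplicates included. A list with at least 5 members tested was set against all other genes with camera in limma 3.58.1 (preset correlation 0.01), with adjustment over 542 tests of lists and comparisons, and again with camera's estimated correlation and with fry. Genes with a locus number alone are in no list. By a rule set in advance, each comparison names every measured marker gene, up to 4 members with the smallest p of each list reported, and the 6 highest and 6 lowest fold changes among named genes with at least 5 CPM in the higher group and groups that do not overlap. Secondary comparisons give fewer, from the top of the same order. Some genes that the rule names are not reported here. Not all lists that passed with the preset correlation alone are given.

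Comparisons, lists, the rule for naming genes and these alternatives were set before the data were examined: DESeq2 1.42.0, RLE size factors in edgeR, no low-count filter, a mean of at least 1 CPM, limma-trend on the log2 of the deposited normalized signal plus 1, the replicate number as a block, a fit of the compared groups alone and each library left out in turn. A fit without Mack1 p77 serum starvation replicate 1 was added later. The procedure was tested on simulated data with the dispersions and depth of 3 comparisons. In the Mack1 p27 serum starvation comparison it recovered 67% of 94 genes changed 2-fold and 84.7% of 98 changed 4-fold, in Mack2 95.9% of 98 and 100% of 99, and in the comparison of the lines 75.8% of 95 and 89.7% of 97. It called 9 of 15045, 13 of 13441 and 14 of 14085 unchanged genes. Far fewer simulated genes changed than the 64.3, 77.7 and 56.5% called in the data, so false calls at those shares were not tested. A planted list of 30 genes shifted 1.5-fold had p of 3.02e-29, 2.35e-45 and 2.16e-22, and a random list 0.902, 0.741 and 0.834. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.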

Results

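RNA from 2 continuous cell lines grown from mackerel skeletal muscle, Mack1 and Mack2, was sequenced in 32 libraries that fall into 10 groups. Mack1 gave 8 groups of 3 libraries: cultures labelled p27, before immortalization, and p77, after it, were each taken in proliferation, serum starvation, serum reduction and lipid loading. Mack2 gave 2 groups of 4 libraries, labelled p2 and p180, both in proliferation. Proliferating cells were kept in growth medium with 20% serum and FGF2, a growth factor that keeps muscle precursors dividing. For serum starvation, confluent cultures were left unfed, and for serum reduction they were given medium with 2.5% serum. For lipid loading, confluent cultures were kept in growth medium with insulin, IBMX (which raises cyclic AMP), dexamethasone (a glucocorticoid) and a lipid mixture. Total counts per library ranged from 16.9 M to 32.01 M, with a mean of 23.8 ± 3.96 M, and the 10 most abundant genes held 9.97 ± 1.46% of them (SD, n = 32). Values after gene names are log2 fold changes ± SE from edgeR's quasi-likelihood test, p-values are Benjamini-Hochberg adjusted, and CPM are means ± SD. Ratios with a range in place of an SE are total counts with a 95% counting interval, and both these and lower bounds cover counting error only. Counts of list members were the same adjusted over the list alone, and medians the same with genes at their bound, or for differences of differences with a floor of 3 counts for groups at 0, unless given. The p-values measure the spread between these libraries alone, which may be technical, and fish duplicates of a gene can share reads.

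Among Mack1 libraries, the first principal component (55.9% of the variance of log2 CPM) parted the proliferating libraries from those of the other states, and the second (17.2%) parted lipid loading from serum starvation and serum reduction. In Mack2 the first component (94.2%) parted p180 from p2. MyoD (myod1), the transcription factor that commits cells to the muscle lineage, stood at 32.2 ± 2.82 CPM in proliferating p27 cultures and 20.2 ± 1.71 CPM in proliferating p77 cultures (n = 3 each).

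**Figure D1:**
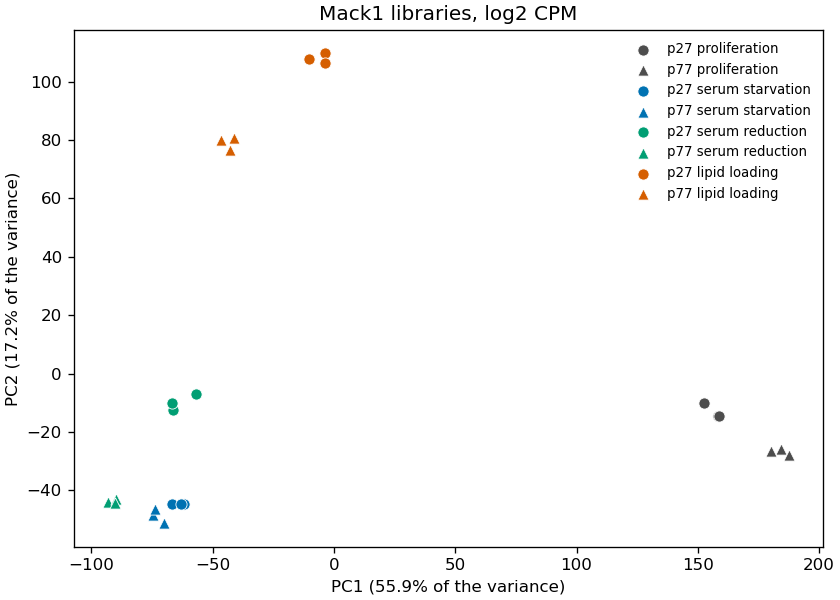
Mack1 libraries on the first 2 principal components of log2 CPM (55.9% and 17.2% of the variance), 1 point per library, 3 per group, colour for the state and marker for the stage. Proliferating libraries lie alone on the right, and lipid loading libraries lie above the other states.

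The first question was how cultures labelled p27 changed when confluent cells were starved of serum. Myogenin (myog, gene 133977390), the transcription factor that starts terminal muscle differentiation, rose 218-fold, from 1.89 ± 0.237 CPM in proliferation to 413 ± 4.65 CPM in serum starvation (n = 3 each). Its log2 fold change was 7.77 ± 0.25, with an adjusted p of 6.93e-20. Genes of the sarcomere, the contractile unit of muscle, rose together: 60 of 63 rose and 2 fell, median 7.63, 6.59 with genes at their bound, camera adjusted p = 8.81e-59. The cardiac-type actin actc1a reached 5200 ± 238 CPM from 10.4 ± 0.515 CPM. Genes of cell division moved the other way: 97 of 104 fell and 1 rose, 100 and 1 adjusted over the list alone, median -1.94, camera adjusted p = 4.2e-16, adjusted p = 0.0811 with an estimated correlation.

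Of the sarcomere genes, those with the smallest p were actc1a (8.97 ± 0.15), mybphb (9.38 ± 0.18), cavin4a (8.29 ± 0.18) and actn3b (9.37 ± 0.21), with a largest adjusted p of 7.69e-23. In the list of muscle differentiation and cell fusion, 33 of 37 rose and 3 fell, median 4.36, camera adjusted p = 2.75e-40. In the lead were srl (7.81 ± 0.14), cdh15 (3.67 ± 0.07), unc45b (6.27 ± 0.14) and bin1b (9.70 ± 0.22). The leading cell division genes were cks1b (-2.40 ± 0.11), mcm2 (-2.03 ± 0.10), tpx2 (-1.90 ± 0.10) and pcna (-2.43 ± 0.13). Among genes of FoxO signalling, muscle atrophy and autophagy, 37 of 62 rose and 6 fell, median 0.54, 0.51 with genes at their bound, camera adjusted p = 6.7e-05. The ubiquitin ligases of muscle wasting fbxo32 (3.52 ± 0.10) and trim63b (3.11 ± 0.11) came first. They were followed by txnipa (2.20 ± 0.08) and ulk2 (2.31 ± 0.09). Folding factors of the endoplasmic reticulum fell: 25 of 28 fell and 2 rose, median -1.43, camera adjusted p = 2.14e-10. In order of p the first were p4hb (-2.09 ± 0.07), hyou1 (-1.93 ± 0.09), pdia3 (-1.91 ± 0.09) and sec61b (-1.82 ± 0.09). Targets of cyclic AMP signalling mostly rose (18 of 26 rose and 4 fell, median 1.43, camera adjusted p = 0.00269, adjusted p = 0.122 with an estimated correlation). First by p came fosab (5.41 ± 0.16), an immediate early gene. For smooth muscle and myofibroblast genes 21 of 35 fell and 9 rose, 21 and 10 adjusted over the list alone, median -1.04, camera adjusted p = 0.000718, adjusted p = 0.222 with an estimated correlation. The striated and smooth muscle tropomyosin tpm2 (8.93 ± 0.23) went against smtnb (-4.45 ± 0.13), cnn2 (-2.55 ± 0.09) and lmod1b (-3.09 ± 0.11). Neither the extracellular matrix list (28 of 65 rose, 28 fell, camera adjusted p = 0.604) nor the fat storage list (17 of 36 rose, 14 fell, camera adjusted p = 0.602) passed as a group.

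Of the genes named in advance as markers of muscle, fat, cell cycle arrest and immortalization, myod1 (1.09 ± 0.09), pax7a (2.32 ± 0.81) and myf5 (at least 17.3-fold higher) rose, as did myog. The cyclin-dependent kinase inhibitors cdkn1a (-1.28 ± 0.10) and cdkn2a/b (-1.57 ± 0.21) fell, as did the fat cell genes fabp4a (-4.17 ± 0.80), plin2 (-1.47 ± 0.13) and pparg (-1.14 ± 0.49). The largest adjusted p among these called genes was 0.0444. Telomerase reverse transcriptase (tert) did not pass (-0.96 ± 0.46, adjusted p = 0.0691), nor did cebpa (adjusted p = 0.153), which had no count in proliferation and 0.0549 ± 0.0485 CPM in starvation. The call changed with another choice for pparg (adjusted p = 0.104 with only the groups compared fitted, 0.222 without p27 proliferation replicate 1 and 0.242 without p27 serum starvation replicate 3) and tert (adjusted p = 0.0379 with only the groups compared fitted and 0.0327 without p27 serum starvation replicate 3). It was lost for pax7a (adjusted p = 0.0883 with no low-count filter, 0.0517 and 0.0773 without p27 proliferation replicate 1 and 3 in turn and 0.0529 and 0.0928 without p27 serum starvation replicate 1 and 2 in turn). The highest changes were in dhrs7ca (at least 894-fold higher), camk2a (at least 811-fold higher), ampd3b (at least 713-fold higher), rap1gap2a (at least 625-fold higher), stbd1 (at least 576-fold higher) and asb10 (at least 534-fold higher). At the other end stood heyl (at least 235-fold lower), ism2b (at least 139-fold lower), acanb (-9.93 ± 0.35), ncf4 (-9.23 ± 0.57), nog2 (-8.23 ± 0.36) and il11a (-7.82 ± 0.46). In all, 10087 of 15683 genes passed the test, 5377 upward and 4710 downward, of which 3023 and 2498 by at least 2-fold. The proliferating cultures are not stated to be confluent, so density and serum differ together in this comparison and in the other comparisons with proliferation.

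Serum reduction was the other condition for muscle differentiation, and it was set against proliferation at p27 to see whether it brought on the same genes. Of the sarcomere list 60 of 63 rose and 2 fell, median 8.41, 7.88 with genes at their bound, camera adjusted p = 1.31e-73. The myosin binding protein mybphb stood at 1430 ± 213 against 1.88 ± 0.385 CPM (n = 3 each, 9.57 ± 0.18, adjusted p = 6.28e-24). It was followed by actc1a (6.90 ± 0.14), actn3b (10.59 ± 0.22) and myom1a (10.15 ± 0.23). Differentiation and fusion genes rose as well (32 of 37 rose and 3 fell, median 5.42, 5.20 with genes at their bound, camera adjusted p = 6.62e-43). In the lead were srl (8.03 ± 0.14), unc45b (7.64 ± 0.15), atp2a1 (10.52 ± 0.23) and klhl31 (5.42 ± 0.12). Genes of cell division fell: 99 of 104 fell and 1 rose, 101 and 2 adjusted over the list alone, median -2.65, camera adjusted p = 2.99e-33. Replication genes were in the lead, mcm2 (-3.02 ± 0.11), mcm5 (-4.83 ± 0.18), tyms (-4.11 ± 0.16) and hells (-4.17 ± 0.16).

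The FoxO, atrophy and autophagy list rose (42 of 62 rose and 7 fell, median 0.67, camera adjusted p = 7.01e-06). Muscle ubiquitin ligases were again among the first, trim63b (3.22 ± 0.11), ulk2 (2.66 ± 0.09), sesn1 (2.52 ± 0.09) and fbxo32 (2.49 ± 0.10). Heat shock genes were mostly higher: 14 of 24 rose and 5 fell, 15 and 5 adjusted over the list alone, median 0.51, camera adjusted p = 0.00454, adjusted p = 0.186 with an estimated correlation. They were led by hspa1b (9.12 ± 0.25), hsp90aa1.1 (8.48 ± 0.24), hspb8 (2.96 ± 0.10) and bag3 (2.82 ± 0.13). Fatty acid oxidation genes moved up as a group (25 of 35 rose and 6 fell, median 0.45, camera adjusted p = 0.00647, adjusted p = 0.212 with an estimated correlation). First came pdk2a (at least 410-fold higher), ppargc1a (1360-fold higher, interval 244 to 53800), acadsb (1.94 ± 0.11) and pdk4 (4.77 ± 0.27). In the extracellular matrix list 38 of 65 rose and 20 fell, median 0.94, camera adjusted p = 0.00154, adjusted p = 0.414 with an estimated correlation. Its leading genes were thbs2a (7.02 ± 0.17), elna (4.72 ± 0.14) and sparc (1.94 ± 0.07) and, downward, fbln1 (-2.43 ± 0.09). Endoplasmic reticulum folding genes fell (22 of 28 fell and 3 rose, 23 and 3 adjusted over the list alone, median -1.01, camera adjusted p = 8.42e-06, adjusted p = 0.0837 with an estimated correlation). First came creld2 (-2.04 ± 0.11), sec61b (-1.58 ± 0.09), p4hb (-1.20 ± 0.07) and canx (-1.21 ± 0.08).

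Of the marker genes, myog (6.76 ± 0.25), cebpa (at least 33.2-fold higher), myf5 (at least 2.88-fold higher) and cdkn1a (0.45 ± 0.09) rose and cdkn2a/b (-0.67 ± 0.20) and plin2 (-0.41 ± 0.12) fell, with a largest adjusted p of 0.0177. Those that did not pass were myod1 (-0.02 ± 0.09), fabp4a (-0.49 ± 0.58), pax7a (0.61 ± 0.82), pparg (-0.91 ± 0.47) and tert (-1.0 ± 0.46), with adjusted p from 0.0604 to 0.863. Calls that changed with another choice were those of myf5 (adjusted p = 0.166 without p27 serum reduction replicate 1), pparg (adjusted p = 0.0159 without p27 serum reduction replicate 1) and tert (adjusted p = 0.0309 by limma-trend on the deposited normalized values and 0.00997 without p27 serum reduction replicate 3). Largest rises were those of ampd3b (at least 1950-fold higher), stbd1 (at least 1460-fold higher), asb10 (at least 980-fold higher), obscna (at least 846-fold higher), rap1gap2a (at least 751-fold higher) and tfeb (at least 730-fold higher). The deepest falls were ism2b (474-fold lower, interval 84.5 to 18800), bicdl1 (-5.73 ± 0.47), heyl (-5.51 ± 0.47), ncf4 (-5.02 ± 0.39), hmga1a (-4.99 ± 0.20) and gins2 (-4.96 ± 0.28). The test passed 9674 of 15683 genes in serum reduction, 5085 upward and 4589 downward, of which 3025 and 2035 by at least 2-fold.

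Lipid loading was the condition for fat cell differentiation, and in p27 cultures the lipid droplet coat gene plin2 (gene 134005995) rose 4.99-fold, from 166 ± 1.48 to 827 ± 28.3 CPM (n = 3 each). The log2 fold change was 2.32 ± 0.13, adjusted p = 1.22e-14. Lipoprotein lipase and its inhibitor rose further, lpla (6.22 ± 0.13) and angptl4 (6.78 ± 0.19), as did the fatty acid binding protein fabp3 (2.13 ± 0.08). The fat cell regulator pparg did not pass (-0.41 ± 0.46, adjusted p = 0.453), and neither did fabp4a (-0.86 ± 0.60, adjusted p = 0.215). As a group the fat cell list did not pass with camera: 14 of 36 rose and 9 fell, median 0.06, mean 1.25, camera adjusted p = 0.0913. It passed with fry, at adjusted p = 6.56e-12. Muscle genes rose in this state too, with 61 of 63 sarcomere members higher and myog 16.8-fold higher (4.07 ± 0.24, adjusted p = 5.85e-14).

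In the sarcomere list 61 of 63 rose and 1 fell, median 6.08, 5.95 with genes at their bound, camera adjusted p = 5e-54. In the lead were actc1a (5.59 ± 0.13), mybphb (7.32 ± 0.17), actn3b (7.71 ± 0.21) and tpm2 (7.38 ± 0.22). Among differentiation and fusion genes 29 of 37 rose and 5 fell, median 2.34, camera adjusted p = 1.38e-19. First came srl (5.29 ± 0.13), casq2 (7.03 ± 0.21), atp2a1 (7.62 ± 0.23) and bin1b (7.02 ± 0.22). Cell division genes fell (98 of 104 fell and 0 rose, median -2.83, camera adjusted p = 3.88e-38). The leading ones were tpx2 (-2.87 ± 0.10), anln (-3.88 ± 0.14), mcm2 (-2.91 ± 0.11) and mki67 (-2.94 ± 0.12). Glucocorticoid response genes rose: 22 of 30 rose and 6 fell, median 1.19, camera adjusted p = 0.000139. The liver enzyme tat (-6.49 ± 0.15) went the other way from angptl4 (6.78 ± 0.19), sesn1 (2.88 ± 0.09) and ddit4 (3.18 ± 0.11). Sterol synthesis genes were higher (19 of 26 rose and 2 fell, median 1.29, camera adjusted p = 0.000201, adjusted p = 0.0528 with an estimated correlation): the rate-limiting reductase hmgcra (2.80 ± 0.12) and acat2 (1.91 ± 0.09) came first. The extracellular matrix list rose: 47 of 65 rose and 11 fell, median 1.93, camera adjusted p = 4.62e-16. Periostin, osteonectin and elastin were among postnb (8.0 ± 0.16), sparc (2.85 ± 0.07), serpinf1 (7.13 ± 0.20) and elna (5.05 ± 0.14). Respiratory chain genes were lower (38 of 49 fell and 1 rose, median -0.65, camera adjusted p = 0.0016, adjusted p = 0.723 with an estimated correlation). The amounts were small, as in sdha (-0.86 ± 0.08), sdhdb (-0.80 ± 0.08), ndufs7 (-0.76 ± 0.08) and ndufb5 (-0.85 ± 0.10). FoxO, atrophy and autophagy genes rose (38 of 62 rose and 6 fell, 39 and 7 adjusted over the list alone, median 0.62, camera adjusted p = 7.6e-05).

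Other marker genes that rose were cebpa (at least 51.8-fold higher), myf5 (at least 35.1-fold higher) and myod1 (0.45 ± 0.09), and tert (-2.41 ± 0.51) fell, with a largest adjusted p of 0.000179. Values that did not pass were cdkn1a (-0.04 ± 0.09), cdkn2a/b (-0.01 ± 0.20) and pax7a (1.08 ± 0.82), with adjusted p from 0.257 to 0.96. The top of the range held pygma (12400-fold higher, interval 2230 to 491000), pdk2a (at least 458-fold higher), pgam2 (3640-fold higher, interval 1010 to 30100), ampd3b (at least 325-fold higher), kcne4 (at least 263-fold higher) and stbd1 (at least 235-fold higher). The bottom held acanb (-7.60 ± 0.29), islr2 (-6.53 ± 0.36), tat (-6.49 ± 0.15), lpar2b (-6.32 ± 0.36), hgd (-5.73 ± 0.47) and ttc36 (-5.39 ± 0.36). Lipid loading differed from proliferation in 10156 of 15683 genes tested, 5385 upward and 4771 downward, of which 3333 and 1905 by at least 2-fold. Since several compounds and confluence act together in this state, no change can be assigned to one of them.

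**Figure D2:**
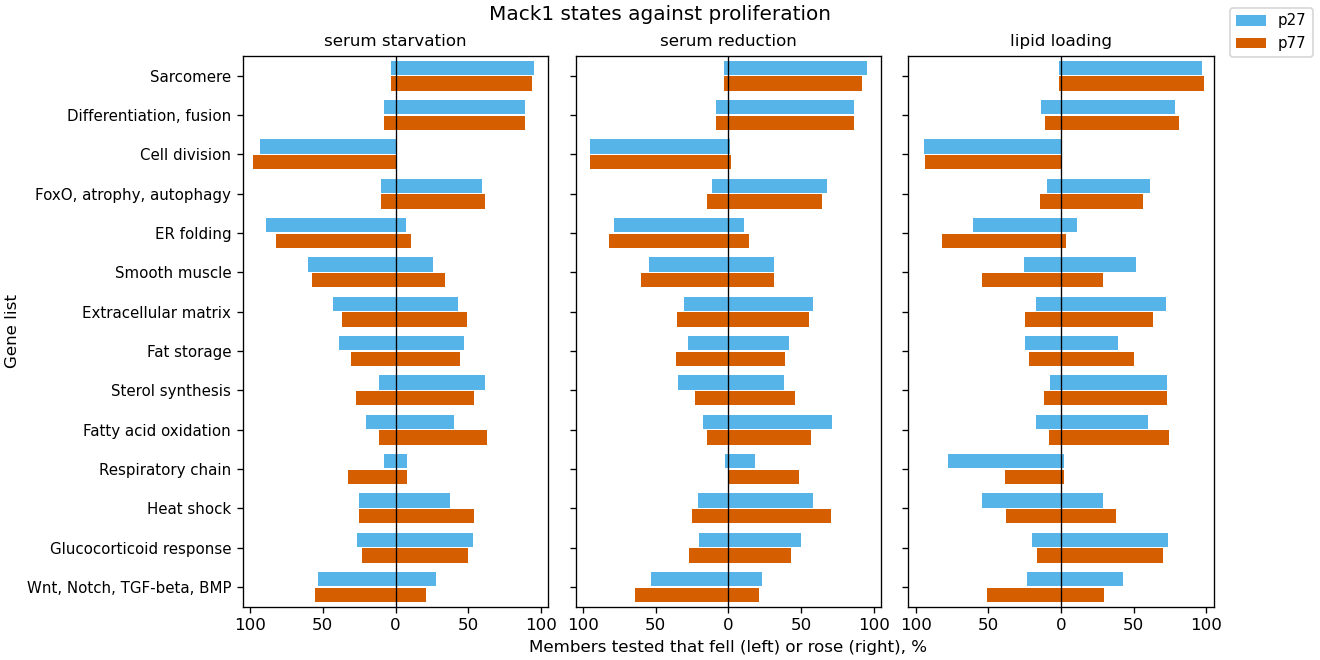
Members of 14 fixed gene lists that rose (right) or fell (left) at an adjusted p under 0.05 in p27 and p77 Mack1 cultures against proliferation, as a percentage of the members tested, 1 panel per state and 1 bar per stage. Sarcomere and fusion genes extend to the right and cell division genes to the left in all 6 comparisons.

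Cultures labelled p77 were put through the same states after immortalization. Myogenin again rose from proliferation, by 10.87 ± 0.33 in serum starvation, 10.43 ± 0.33 in serum reduction and 8.89 ± 0.34 in lipid loading (n = 3 each, largest adjusted p = 2.08e-18). Its level went from 0.165 ± 0.0879 CPM to 231 ± 5.57 CPM in reduction, 79.6 ± 10.9 CPM in lipid loading and 171, 392 and 379 CPM in the 3 libraries of starvation. In that order of states, sarcomere genes rose: 59, 58 and 62 of 63 rose and 2, 2 and 1 fell, medians 9.35, 10.21 and 9.54, or 8.63, 9.34 and 7.85 with genes at their bound, camera adjusted p = 9.67e-66, 7.61e-68 and 2.79e-76. The first was actc1a, at 11.49 ± 0.17, 10.21 ± 0.17 and 9.61 ± 0.16. For fusion genes, 33, 32 and 30 of 37 rose and 3, 3 and 4 fell (33, 33 and 30 rose and 3, 3 and 5 fell adjusted over the list alone), camera adjusted p = 1.41e-49, 4.95e-45 and 2.41e-42. The calcium store gene srl rose by 11.41 ± 0.18, 11.95 ± 0.18 and 10.20 ± 0.18. Cell division genes fell: 102, 99 and 97 of 104 fell and 1, 2 and 1 rose (2, 2 and 1 rose adjusted over the list alone), medians -2.34, -2.65 and -1.75, camera adjusted p = 1.56e-20, 6.37e-22 and 6.54e-16, with an estimated correlation adjusted p = 0.0543 in serum starvation and adjusted p = 0.0737 in lipid loading. The spindle gene tpx2 (-2.56 ± 0.10) led in starvation, mcm2 (-3.19 ± 0.11) in reduction and tpx2 (-2.37 ± 0.10) in lipid loading. Endoplasmic reticulum folding genes fell as well: 23, 23 and 23 of 28 fell and 3, 4 and 1 rose (23, 23 and 24 fell adjusted over the list alone), camera adjusted p = 2.55e-09, 1.22e-07 and 1.63e-06, with an estimated correlation adjusted p = 0.0586 in lipid loading. The muscle ligase gene fbxo32 rose by 4.76 ± 0.11, 4.05 ± 0.11 and 3.52 ± 0.10.

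Lipid loading raised plin2 (2.16 ± 0.13), fabp3 (2.66 ± 0.08), angptl4 (4.43 ± 0.16) and lpla (2.43 ± 0.11) in p77 cultures, and lowered pparg (-1.86 ± 0.38). Glucocorticoid targets rose (21 of 30 rose and 5 fell, camera adjusted p = 0.00154). So did sterol synthesis (19 of 26 rose and 3 fell, camera adjusted p = 0.0302, adjusted p = 0.248 with an estimated correlation) and matrix genes (41 of 65 rose and 16 fell, camera adjusted p = 4.28e-07, adjusted p = 0.196 with an estimated correlation). Under serum starvation cdkn1a (-2.0 ± 0.10), cdkn2a/b (-1.18 ± 0.22), plin2 (-1.26 ± 0.13), fabp4a (278-fold lower, interval 49.5 to 11000) and tert (-1.43 ± 0.45) fell, while myod1 (1.37 ± 0.09) and myf5 (at least 42.8-fold higher) rose. Under serum reduction myod1 (1.12 ± 0.09) and myf5 (at least 46.2-fold higher) rose, and fabp4a (-4.12 ± 0.66), plin2 (-0.98 ± 0.13) and pparg (-1.25 ± 0.37) fell. With lipid loading myod1 (1.32 ± 0.09), myf5 (at least 92.3-fold higher) and cebpa (at least 11.4-fold higher) rose. At the top of the ranges stood the calcium release channel gene ryr1b (at least 4440-fold higher) in starvation, ryr1b (at least 4850-fold higher) in reduction and pygma (at least 12000-fold higher) in lipid loading. In the same order, at the bottom were id4 (at least 252-fold lower), ptprea (at least 210-fold lower) and plcd1b (694-fold lower, interval 237 to 3370). The test passed 10498, 10787 and 10305 genes (5565, 5779 and 5513 upward). The fold changes of p77 and p27 cultures, which share no library, correlated across 15683 genes with Pearson's r of 0.86, 0.87 and 0.83 (Spearman's rho 0.85, 0.84 and 0.83). Genes are not independent replicates. In starvation 4479 genes rose and 3965 fell in both, where independent lists would share 1908 and 1482, and 99 moved in opposite directions. One library, p77 serum starvation replicate 1, stood apart from its group, and without it 10595 genes passed.

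The comparison of p77 with p27 asks how immortalized cells differed from their predecessors while both were proliferating. Muscle differentiation genes were lower in p77: myog fell to 0.165 ± 0.0879 from 1.89 ± 0.237 CPM (n = 3 each, -3.50 ± 0.54, adjusted p = 1.35e-05). Of the fusion list 25 of 37 were lower and 1 higher, 27 and 1 adjusted over the list alone, median -1.80, -1.31 with genes at their bound, camera adjusted p = 1.3e-21. Sarcomere genes were also lower (34 of 63 lower and 2 higher, 35 and 2 adjusted over the list alone, median -1.96, -1.47 with genes at their bound, camera adjusted p = 1.38e-17, adjusted p = 0.0848 with an estimated correlation). The skeletal and cardiac actins acta1a (-4.83 ± 0.18) and actc1b (-3.46 ± 0.15) came first. The fat cell regulator pparg (gene 133978082) was 9.5-fold higher, at 9.49 ± 1.24 against 0.992 ± 0.37 CPM (3.25 ± 0.42, adjusted p = 9.6e-07). Alkaline phosphatase of bone and cartilage (alpl) was 17.1-fold higher (4.09 ± 0.14), at 253 ± 8.29 against 14.8 ± 1.96 CPM.

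Fusion genes with the smallest p were jam2a (-2.90 ± 0.12), chrng (-2.75 ± 0.14), unc45b (-2.79 ± 0.15) and smyd1b (-2.04 ± 0.12). After the actins, the sarcomere list continued with synpo2lb (-2.08 ± 0.11) and actc1a (-2.96 ± 0.16). Smooth muscle and myofibroblast genes were lower (19 of 35 lower and 2 higher, 20 and 2 adjusted over the list alone, median -0.37, camera adjusted p = 6.43e-06, adjusted p = 0.1 with an estimated correlation). The first were tagln (-1.23 ± 0.07), cav1 (-1.74 ± 0.14), myl9b (-0.73 ± 0.07) and acta2 (-1.60 ± 0.20). Amino acid synthesis and integrated stress response genes were lower (29 of 44 lower and 3 higher, 32 and 4 adjusted over the list alone, median -0.37, camera adjusted p = 3.67e-08). Among them were the transporter slc1a4 (-4.59 ± 0.33), shmt2 (-0.77 ± 0.07) of serine and glycine metabolism and asparagine synthetase asns (-0.73 ± 0.08). Of neural and glial genes 4 of 13 were lower and 0 higher, median 0.00, mean -0.42, camera adjusted p = 0.00226. The one with the smallest p was nes (-3.49 ± 0.10), whose product nestin is also an intermediate filament of muscle precursors. Bone and cartilage genes were higher: 6 of 16 higher and 2 lower, 8 and 3 adjusted over the list alone, median 0.63, camera adjusted p = 1.61e-05. They were led by alkaline phosphatase and a cartilage transcription factor in alpl (4.09 ± 0.14), sox6 (4.25 ± 0.30), msx1a (1.51 ± 0.18) and phex (2.25 ± 0.30). Sterol synthesis genes were higher (13 of 26 higher and 0 lower, median 0.39, camera adjusted p = 0.000563, adjusted p = 0.0661 with an estimated correlation). They were so by less than 2-fold in dhcr7 (0.62 ± 0.09), msmo1 (0.77 ± 0.12) and fdps (0.76 ± 0.12) and by more in fdft1 (1.45 ± 0.24). Cell division genes were slightly higher (17 of 104 higher and 1 lower, 12 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 0.000293, adjusted p = 0.424 with an estimated correlation). Examples were dnmt1 (0.72 ± 0.13), mcm2 (0.46 ± 0.10), tyms (0.61 ± 0.13) and mcm7 (0.46 ± 0.11). Their number upward was not firm: 61 with only the groups compared fitted, 29 with p77 serum starvation replicate 1 out of the fit, 9 without p27 proliferation replicate 2 and 9 and 10 without p77 proliferation replicate 2 and 3 in turn. The matrix list was higher on balance (28 of 65 higher and 16 lower, 29 and 16 adjusted over the list alone, median 0.40, camera adjusted p = 0.00251, adjusted p = 0.423 with an estimated correlation). Fibronectin fn1a (-2.82 ± 0.14) came before loxl3b (2.74 ± 0.14) and loxa (1.93 ± 0.10). Fat storage genes also passed upward (8 of 36 higher and 4 lower, 10 and 4 adjusted over the list alone, median 0.06, camera adjusted p = 0.04, adjusted p = 0.076 with an estimated correlation). In the lead were lpla (3.54 ± 0.12) and cebpd (2.80 ± 0.19). Telomere maintenance genes did not pass as a group (median -0.04, camera adjusted p = 0.992).

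Further marker genes higher in p77 were fabp4a (1.89 ± 0.57) and cdkn1a (0.32 ± 0.09). Lower were cdkn2a/b (-1.16 ± 0.21), myod1 (-0.67 ± 0.09), plin2 (-0.81 ± 0.12) and pax7a (19.5-fold lower, interval 3.08 to 813), the last with 1 count in the p77 libraries together. Their largest adjusted p was 0.0229. The value of tert was 0.81 ± 0.44 with an adjusted p of 0.195, and cebpa and myf5 had no count in either group. Calls that changed with another choice were those of cdkn1a (adjusted p = 0.0875 without p27 proliferation replicate 2) and fabp4a (adjusted p = 0.0872 without p27 proliferation replicate 2 and 0.0542 without p77 proliferation replicate 3). The same held for pax7a (adjusted p = 0.0632 with no low-count filter, 0.0556 and 0.0566 without p27 proliferation replicate 1 and 2 in turn and 0.0961 and 0.0896 without p77 proliferation replicate 2 and 3 in turn), while tert (adjusted p = 0.0203 with only the groups compared fitted) gained one. Highest in p77 were ednrba (6.34 ± 1.06), hopx (5.74 ± 0.55), nbl1 (5.61 ± 0.25), hgfb (4.30 ± 0.79), sox6 (4.25 ± 0.30) and itgbl1 (4.21 ± 0.12). Lowest were sphkap (217-fold lower, interval 59.8 to 1800), vcanb (-5.24 ± 0.29), acta1a (-4.83 ± 0.18), slc1a4 (-4.59 ± 0.33), tuba1c (-3.77 ± 0.22) and dysf (-3.69 ± 0.29). The stages differed in 4013 of 15683 genes tested, 1649 upward and 2364 downward, of which 566 and 812 by at least 2-fold. With 1 line and 1 culture history, passage, immortalization and any drift between the stages cannot be separated.

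**Figure D3:**
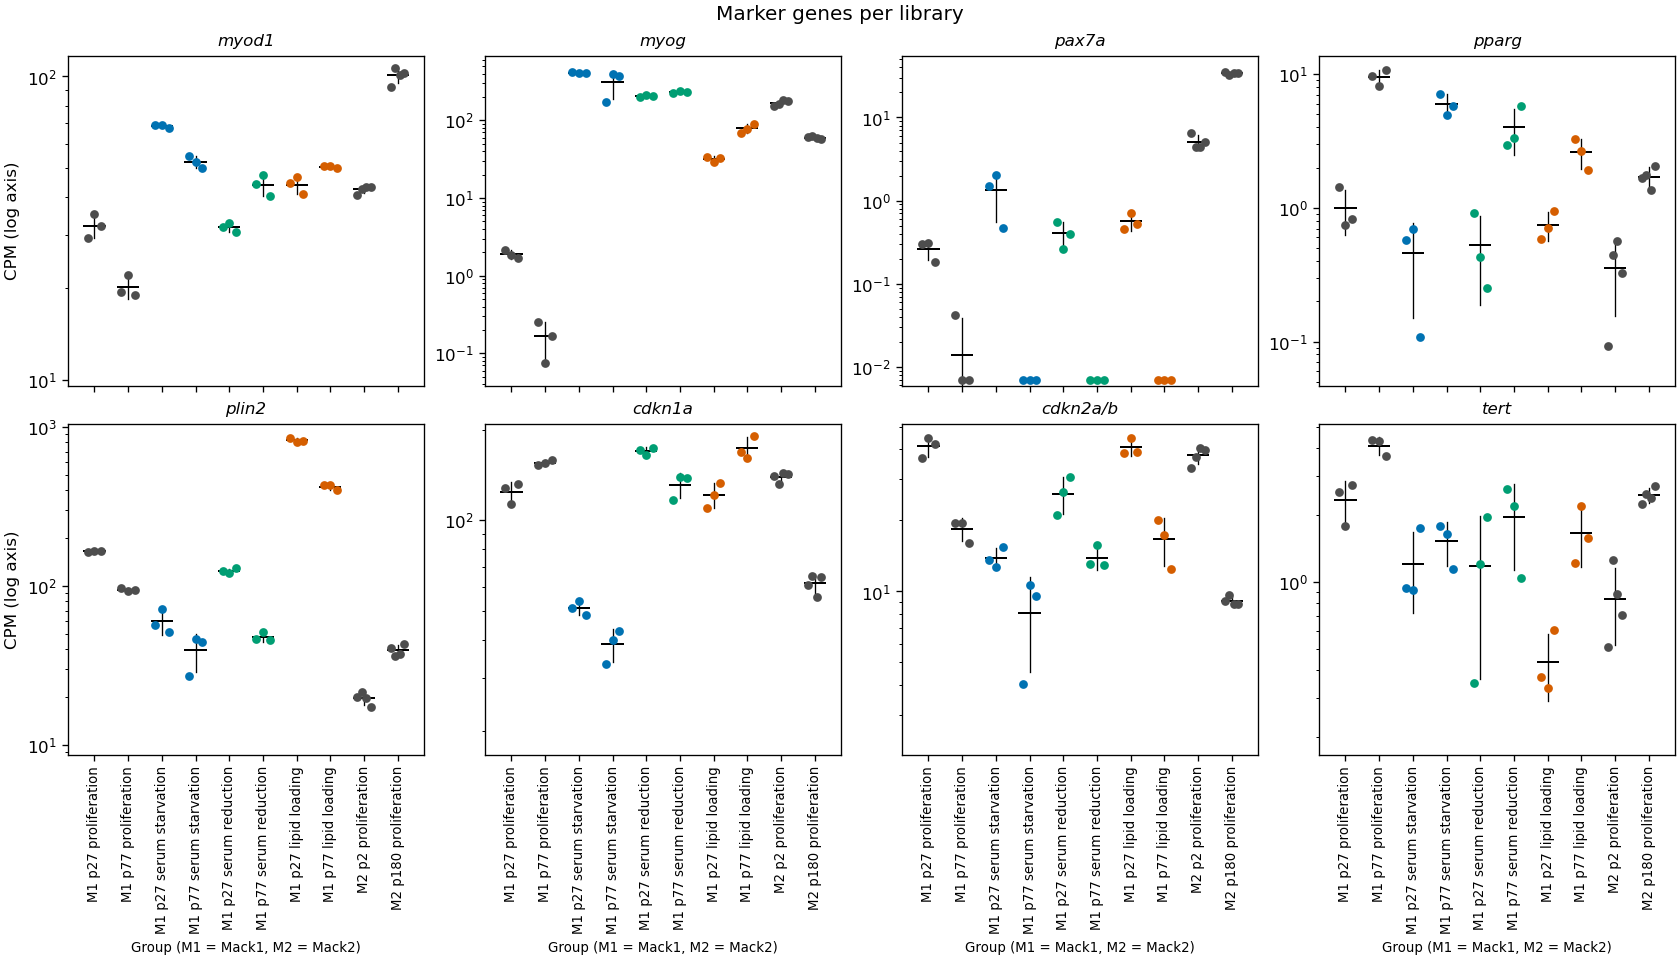
CPM of 8 marker genes in each of the 32 libraries on a log axis (counts of 0 drawn at the lower edge), grouped by line, stage and state, with a bar at the group mean and a line of ±1 SD. Within each Mack1 stage, myogenin is higher in the 3 other states than in proliferation and plin2 is highest in lipid loading.

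The stages also differed within each of the other states. In serum starvation, matrix genes were higher in p77 (34 of 65 higher and 9 lower, 35 and 10 adjusted over the list alone, median 0.69, camera adjusted p = 7.13e-21), led by loxa (2.67 ± 0.10), thbs4b (2.24 ± 0.09) and fbln1 (1.91 ± 0.08). Bone and cartilage genes were higher too (7 of 16 higher and 0 lower, 8 and 0 adjusted over the list alone, median 0.72, camera adjusted p = 2.25e-06). First came alpl (1.81 ± 0.12), tnmd (3.53 ± 0.30), phex (1.69 ± 0.19) and col11a2 (4.39 ± 0.65). Sarcomere genes were higher on balance (26 of 63 higher and 9 lower, 31 and 10 adjusted over the list alone, median 0.36, camera adjusted p = 3.92e-05, adjusted p = 0.397 with an estimated correlation), although the ventricular light chain gene myl2a (-3.60 ± 0.23) led the list. The number upward was 15 by limma-trend on the deposited normalized values and 17 with only the groups compared fitted. The largest single differences were in nbl1 (5.59 ± 0.26) and cilp (4.74 ± 0.21) and, downward, myl2a (-3.60 ± 0.23) and cntf (-3.38 ± 0.53). Here 3345 genes passed (1748 higher in p77, 1597 lower), 1348 when these 2 groups were fitted alone, and 2706 without p77 serum starvation replicate 1.

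In serum reduction, smooth muscle genes were lower in p77 (26 of 35 lower and 3 higher, median -0.96, camera adjusted p = 6.03e-20). First came tagln (-1.78 ± 0.07), lmod1b (-2.20 ± 0.11), cnn2 (-1.38 ± 0.09) and csrp1b (-2.13 ± 0.15). Sterol synthesis genes were higher (17 of 26 higher and 1 lower, 19 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 5.28e-08). First came fdps (1.21 ± 0.12), lss (2.70 ± 0.29), hmgcs1 (0.91 ± 0.10) and nsdhl (1.83 ± 0.21). Sarcomere genes were higher on balance (31 of 63 higher and 7 lower, 33 and 7 adjusted over the list alone, median 0.52, camera adjusted p = 3.14e-07, adjusted p = 0.292 with an estimated correlation). Muscle glycogen phosphorylase, pygma (3.44 ± 0.17), led the list, whose number upward was 18 by limma-trend on the deposited normalized values. Epithelial genes were lower (7 of 12 lower and 0 higher, 8 and 0 adjusted over the list alone, median -0.74, camera adjusted p = 0.000105). The extremes were lrfn5a (5.25 ± 0.46) and nbl1 (4.79 ± 0.26) above p27 and vat1 (-4.47 ± 0.30) and arsj (-4.33 ± 0.30) below it, and 4841 genes passed (2311 higher, 2530 lower). In lipid loading the stages lay furthest apart by count, with 5378 genes (2920 higher, 2458 lower). Sarcomere genes were higher in p77 (53 of 63 higher and 1 lower, median 1.46, camera adjusted p = 1.71e-32). They began with cavin4a (2.04 ± 0.12), myoz2b (1.78 ± 0.11) and mybpc3 (2.80 ± 0.19). Fusion genes were higher too (28 of 37 higher and 4 lower, 29 and 4 adjusted over the list alone, median 1.41, camera adjusted p = 4.36e-25), the first being atp2a1 (3.97 ± 0.14), cdh15 (1.27 ± 0.07) and chrng (2.18 ± 0.12). Cell division genes were higher as well: 92 of 104 higher and 0 lower, 93 and 0 adjusted over the list alone, median 1.29, camera adjusted p = 6.79e-28. In the lead were mcm2 (1.46 ± 0.11), kif20a (1.95 ± 0.14), ccnb1 (2.08 ± 0.16) and top2a (1.70 ± 0.13). Smooth muscle genes were lower (25 of 35 lower and 3 higher, median -1.34, camera adjusted p = 7.92e-31). The first were tagln (-2.33 ± 0.07), lmod1b (-2.77 ± 0.11), csrp1b (-3.49 ± 0.15) and tpm4a (-1.62 ± 0.08). The Wnt, Notch, TGF-beta and BMP list was lower (27 of 47 lower and 4 higher, 28 and 4 adjusted over the list alone, median -0.93, camera adjusted p = 4.01e-11). It began with the BMP antagonist gene grem2a (-3.61 ± 0.22), tgfb1a (-1.53 ± 0.09), skila (-1.59 ± 0.10) and smad6b (-2.40 ± 0.15). The melanin enzyme gene dct (5.44 ± 0.67) and alpl (4.66 ± 0.18) were the furthest above p27, and gdf10a (-5.98 ± 0.42) and heyl (-5.95 ± 0.53) the furthest below.

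Among marker genes, pparg was higher in p77 in every state (3.72 ± 0.45 in starvation, 2.90 ± 0.44 in reduction and 1.80 ± 0.43 in lipid loading). The inhibitor gene cdkn2a/b was lower in every state (-0.77 ± 0.22, -0.90 ± 0.21 and -1.30 ± 0.21), as was plin2 (-0.60 ± 0.13, -1.37 ± 0.13 and -0.97 ± 0.12). The starvation value was not called in every fit for cdkn2a/b (adjusted p = 0.16 with only the groups compared fitted, 0.0545 without p27 serum starvation replicate 3 and 0.0588 without p77 serum starvation replicate 1) and plin2 (adjusted p = 0.114 with only the groups compared fitted). The largest adjusted p of these 9 values was 0.0118. The satellite cell gene pax7a had no count in any of the 3 p77 states and was at least 32.6, 9.25 and 15.7-fold lower than in p27. Stage differences in separate states share no library, and their correlation across 15683 genes ranged from 0.17 (proliferation with lipid loading) to 0.45 (serum reduction with lipid loading).

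Whether the response to a state differed between the stages was tested as the difference itself. For muscle genes the difference, p77 minus p27, was mostly positive: for the sarcomere list, 35, 36 and 41 of 63 were positive and 1, 2 and 0 negative (38, 37 and 41 positive and 2, 2 and 0 negative adjusted over the list alone) in serum starvation, serum reduction and lipid loading, with medians of the difference of 2.43, 2.31 and 3.42, or 2.19, 2.15 and 2.88 with the floor, camera adjusted p = 6.26e-30, 9.17e-25 and 3.11e-40. For fusion genes, 23, 28 and 27 of 37 were positive and 1, 3 and 3 negative (26, 29 and 28 positive adjusted over the list alone), medians 2.55, 2.33 and 3.55, or 1.94, 2.18 and 3.08 with the floor, camera adjusted p = 2.24e-30, 8.18e-26 and 3.22e-42. Myogenin differed by 3.10 ± 0.58, 3.68 ± 0.57 and 4.82 ± 0.55 (n = 3 per group, adjusted p = 0.000431, 1.95e-05 and 1.61e-07). With lipid loading it went from 1.89 ± 0.237 to 31.8 ± 2.57 CPM in p27 and 0.165 ± 0.0879 to 79.6 ± 10.9 CPM in p77. The actin gene acta1a differed by 5.13 ± 0.22, 6.06 ± 0.22 and 4.10 ± 0.22, and the acetylcholine receptor subunit chrng by 3.44 ± 0.19, 4.01 ± 0.19 and 4.92 ± 0.19. These 3 genes stood higher in proliferating p27 than in proliferating p77 cultures, so each difference includes the starting level. For acta1a with lipid loading, 108 ± 17.7 to 220 ± 35.3 CPM in p27 and 3.79 ± 0.972 to 133 ± 12.3 CPM in p77, the level reached was lower in p77. Nor was the mean for myog in starvation higher, at 314 CPM against 413 ± 4.65 CPM in p27.

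In lipid loading, cell division genes fell less in p77 (61 of 104 positive and 0 negative, 75 and 0 adjusted over the list alone, median 0.96, camera adjusted p = 1.03e-14, adjusted p = 0.0941 with an estimated correlation). In the lead were ccnb1 (1.89 ± 0.21), cdc20 (2.0 ± 0.25), kif20a (1.48 ± 0.19) and top2a (1.39 ± 0.18). For the Wnt, Notch, TGF-beta and BMP list the difference was negative (25 of 47 negative and 3 positive, 28 and 4 adjusted over the list alone, median -1.07, camera adjusted p = 2.12e-13). The first were smad6b (-3.68 ± 0.21), smad9 (-4.76 ± 0.37), grem2a (-3.60 ± 0.28) and tgfb3 (-1.62 ± 0.14). It was also negative for smooth muscle genes (21 of 35 negative and 3 positive, 22 and 5 adjusted over the list alone, median -0.83, camera adjusted p = 1.32e-11), as in lmod1b (-2.38 ± 0.15), cald1a (-2.07 ± 0.14) and csrp1b (-2.67 ± 0.20). The same held for endoplasmic reticulum folding genes (14 of 28 negative and 0 positive, 19 and 0 adjusted over the list alone, median -0.40, camera adjusted p = 2.56e-07). In serum starvation, the difference was negative for sterol synthesis genes (10 of 26 negative and 0 positive, 11 and 1 adjusted over the list alone, median -0.49, camera adjusted p = 4.14e-07). Among the lowest p were those of hmgcra (-1.69 ± 0.16), tm7sf2 (-2.08 ± 0.33) and acat2 (-0.72 ± 0.12). The first rose at both stages, from 24.4 ± 2.43 to 147 ± 11 CPM in p27 and 33 ± 1.84 to 61.6 ± 13 CPM in p77. In serum reduction the negative lists were Wnt, Notch, TGF-beta and BMP (18 of 47 negative and 2 positive, 19 and 2 adjusted over the list alone, median -0.58, camera adjusted p = 0.000279) and bone and cartilage (8 of 16 negative and 2 positive, median -0.40, -0.95 with the floor, camera adjusted p = 0.00917). The amino acid list was positive there (23 of 44 positive and 1 negative, 24 and 3 adjusted over the list alone, median 0.37, camera adjusted p = 2.76e-06, adjusted p = 0.0848 with an estimated correlation). Of the other marker genes, the difference passed for cdkn1a (-0.72 ± 0.14) in starvation, cdkn1a (-0.69 ± 0.13), fabp4a (-3.64 ± 0.87), myod1 (1.14 ± 0.12) and plin2 (-0.56 ± 0.18) in reduction and myod1 (0.87 ± 0.12) in lipid loading. The call was not kept in every fit for plin2 (adjusted p = 0.0515 and 0.0513 without p77 serum reduction replicate 1 and 3 in turn) in reduction. The BMP receptor gene bmpr1bb went from 0.363 ± 0.216 to 2.55 ± 0.228 CPM in p27 and 0 ± 0 to 11.6 ± 1.73 CPM in p77 in starvation, the highest difference there. The difference passed for 2132, 3555 and 3696 genes (1365, 1809 and 2154 positive). The count for starvation was 1369 with only its 4 groups fitted and 2223 without p77 serum starvation replicate 1.

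The 2 muscle protocols were set against each other, starvation minus reduction. Heat shock genes were lower in starvation in both stages, in p27 (15 of 24 lower and 1 higher, 16 and 1 adjusted over the list alone, median -0.43, camera adjusted p = 5.09e-10) and in p77 (16 of 24 lower and 1 higher, 19 and 1 adjusted over the list alone, median -0.53, camera adjusted p = 7.87e-15). The chaperone gene hspa1b stood at -3.02 ± 0.16 and -2.82 ± 0.16 (n = 3 per group, adjusted p = 3.23e-14 and 4.96e-13). Glycolysis and hypoxia genes were lower too, in p27 (22 of 41 lower and 4 higher, 27 and 4 adjusted over the list alone, median -0.51, camera adjusted p = 1.24e-07) and p77 (24 of 41 lower and 3 higher, median -0.44, camera adjusted p = 3.42e-11). The glycolytic enzyme genes among them were gpia at -1.25 ± 0.07 and -1.25 ± 0.07 and pfkmb at -3.94 ± 0.24 and -3.93 ± 0.22. The inhibitor of cyclin-dependent kinases cdkn1a was lower in starvation in both, at -1.73 ± 0.10 and -1.76 ± 0.10. Sarcomere genes were lower on balance in p27 (38 of 63 lower and 6 higher, 38 and 7 adjusted over the list alone, median -0.66, -0.57 with genes at their bound, camera adjusted p = 1.61e-05, adjusted p = 0.392 with an estimated correlation). They were lower in p77 too (37 of 63 lower and 4 higher, 37 and 5 adjusted over the list alone, median -0.62, camera adjusted p = 1.83e-13, adjusted p = 0.135 with an estimated correlation). Cell division genes were higher in starved p27 cultures (76 of 104 higher and 2 lower, 85 and 3 adjusted over the list alone, median 0.85, camera adjusted p = 4.37e-16, adjusted p = 0.0774 with an estimated correlation). Sterol synthesis genes were higher in starved p27 cultures (17 of 26 higher and 1 lower, 18 and 2 adjusted over the list alone, median 0.56, camera adjusted p = 5.99e-06). They began with the regulator of the pathway, srebf2 (1.08 ± 0.08), sqlea (2.42 ± 0.23) and ebp (1.33 ± 0.13). In p77 12 of 26 were lower and 5 higher, and the list did not pass with camera (adjusted p = 0.168) but did with fry (adjusted p = 3.98e-04). The highest were thbd (4.84 ± 0.43) and alpl (4.71 ± 0.17) in p27 and edn3b (3.57 ± 0.75) and nfatc2a (3.50 ± 0.28) in p77. The lowest were prss35 (-5.97 ± 0.41) and krt94 (-5.96 ± 0.24) in p27 and synpo2la (-4.61 ± 0.45) and acta2 (-4.00 ± 0.27) in p77. The protocols differed in 5940 genes at p27 (2814 higher in starvation) and 4685 at p77 (2255 higher). The p77 count was 2634 with only these 2 groups fitted and 4456 without serum starvation replicate 1.

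In the second line, p180 cultures were compared with p2 cultures, both proliferating (n = 4 each). Cell division genes were higher in p180 almost throughout: 100 of 104 higher and 0 lower, median 1.79, camera adjusted p = 1.4e-39. The proliferation marker mki67 (gene 134003889) stood at 207 ± 9.88 against 45.1 ± 3.01 CPM (2.20 ± 0.05, adjusted p = 3.58e-15). Collagen I (col1a1b) fell to 407 ± 13.3 from 4010 ± 260 CPM, and matrix genes were lower as a list (48 of 62 lower and 9 higher, median -2.33, camera adjusted p = 1.9e-17, adjusted p = 0.0698 with an estimated correlation). Sarcomere genes were lower as well (50 of 61 lower and 8 higher, median -2.07, camera adjusted p = 1.12e-31), while the lineage factor myod1 was 2.38-fold higher (1.25 ± 0.05, adjusted p = 1.95e-12).

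The cell division genes with the smallest p were anln (1.90 ± 0.04), ccna2 (2.74 ± 0.05), mcm5 (2.41 ± 0.05) and mki67 (2.20 ± 0.05). Genes of telomerase and telomere maintenance were higher (22 of 24 higher and 0 lower, median 0.86, camera adjusted p = 0.000157). Telomerase ribonucleoprotein genes led them, gar1 (1.46 ± 0.04), wrap53 (1.5 ± 0.06) and dkc1 (0.83 ± 0.04). Among matrix genes the first were pcolce2b (-5.07 ± 0.07), col1a1b (-3.30 ± 0.05), loxl2b (-6.25 ± 0.09) and loxa (-5.53 ± 0.09). Sarcomere genes began with tpm2 (-3.97 ± 0.04), mylpfb (-4.00 ± 0.04), mybphb (-3.36 ± 0.04) and tnnt3a (-3.07 ± 0.04). Fusion genes were lower (22 of 36 lower and 11 higher, median -0.51, camera adjusted p = 0.000225, adjusted p = 0.251 with an estimated correlation). Genes of the calcium store and transverse tubules led them, bin1b (-3.23 ± 0.05), casq2 (-2.61 ± 0.05), jph2 (-3.43 ± 0.08) and smyd1a (-2.17 ± 0.05). Glycolysis and hypoxia genes were lower (32 of 41 lower and 8 higher, median -0.63, camera adjusted p = 1.61e-05, adjusted p = 0.184 with an estimated correlation). They began with aldoab (-2.42 ± 0.04), pkmb (-2.44 ± 0.04), ndrg1a (-3.47 ± 0.06) and p4ha1b (-1.42 ± 0.04). Sterol synthesis genes were higher (19 of 24 higher and 4 lower, median 0.75, camera adjusted p = 0.00343, adjusted p = 0.248 with an estimated correlation). First by p were lbr (2.32 ± 0.06) and srebf2 (1.2 ± 0.04), and then hmgcra (-2.19 ± 0.08) in the other direction.

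Marker genes moved both ways. Higher in p180 were pax7a (2.71 ± 0.09), pparg (2.34 ± 0.33), tert (1.60 ± 0.23) and plin2 (1.01 ± 0.07), besides myod1, so that the catalytic subunit of telomerase reached 2.46 ± 0.199 from 0.84 ± 0.32 CPM. Lower were fabp4a (-3.90 ± 0.44), cdkn2a/b (-2.05 ± 0.07), myog (-1.49 ± 0.05) and cdkn1a (-1.18 ± 0.05), and the largest adjusted p of these was 1.13e-05. The greatest rises were those of apba2b (650-fold higher, interval 116 to 25700), meltf (8.59 ± 0.12), tmtc2b (5.59 ± 0.20), tmeff2a (5.31 ± 0.14), shisal1b (5.28 ± 0.11) and trabd2a (4.76 ± 0.06). The greatest falls were in ntn5 (at least 677-fold lower), rapgef3 (at least 545-fold lower), prss35 (at least 531-fold lower), ism2a (at least 381-fold lower), rasl12 (at least 367-fold lower) and znf703 (at least 350-fold lower), all without a count in p180. Between the Mack2 stages, 10721 of 13805 genes differed, 5326 upward and 5395 downward, of which 1207 and 2348 by at least 2-fold. Batch labels place 1 p2 library, replicate 4, apart from the other 7, and without it 10466 genes passed.

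**Figure D4:**
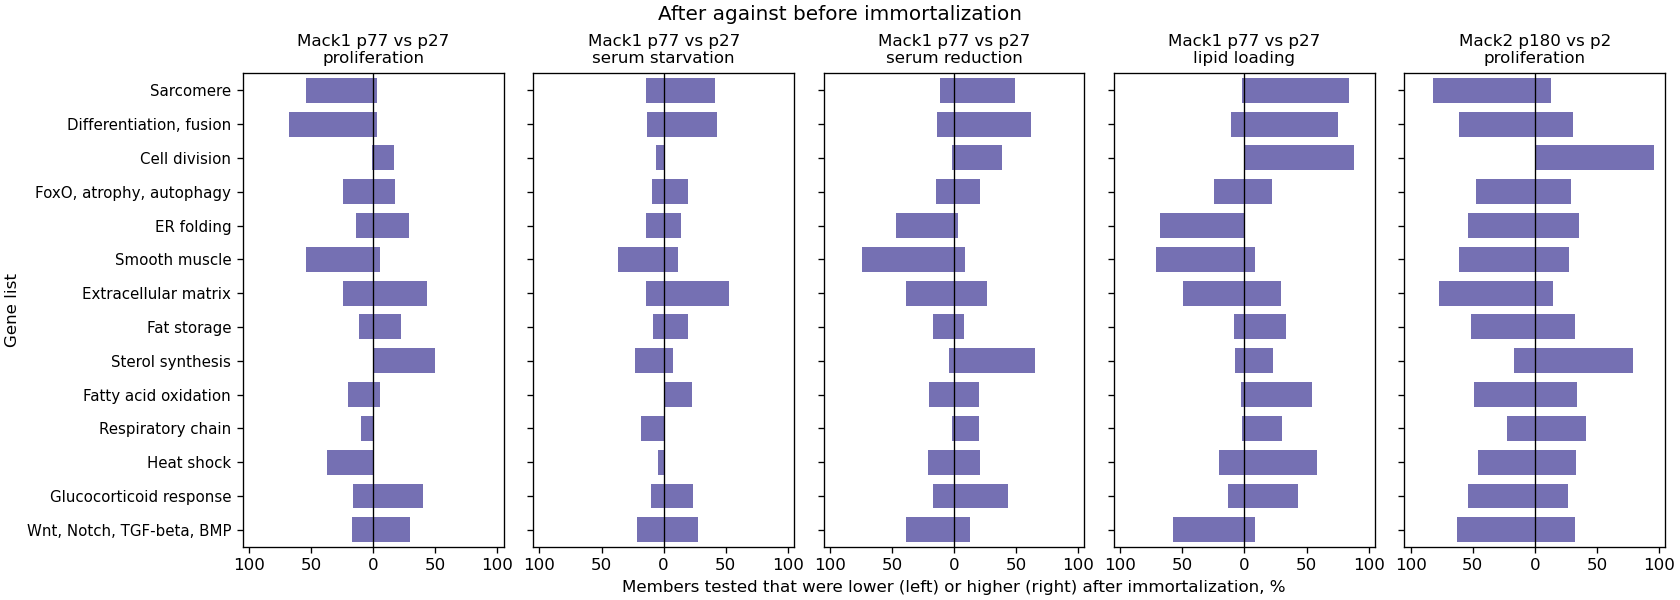
Members of 14 fixed gene lists that were higher (right) or lower (left) after immortalization at an adjusted p under 0.05, as a percentage of the members tested, in Mack1 p77 against p27 in each of 4 states and in Mack2 p180 against p2. Cell division genes lie far to the right in Mack2 and in Mack1 lipid loading.

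Finally, the change between stages in Mack2 was set against that in Mack1, all in proliferation, as a difference of differences. Cell division genes rose more in Mack2 (101 of 104 positive and 0 negative, median 1.54, camera adjusted p = 8.35e-34). They began with anln (1.84 ± 0.06), ccna2 (2.38 ± 0.08), mcm4 (2.22 ± 0.08) and mki67 (2.01 ± 0.08) (n = 4 and 3 per group, largest adjusted p = 1.06e-14). Telomere maintenance genes did likewise (20 of 24 positive and 0 negative, 21 and 0 adjusted over the list alone, median 0.88, camera adjusted p = 5.61e-05). First came wrap53 (1.76 ± 0.08), nop10 (1.43 ± 0.08), gar1 (1.48 ± 0.09) and dkc1 (0.96 ± 0.08). Matrix genes moved the other way (43 of 64 negative and 10 positive, 44 and 11 adjusted over the list alone, median -2.88, -2.78 with the floor, camera adjusted p = 1.07e-32). Collagen I and its crosslinking enzyme led, as col1a1b (-3.84 ± 0.07), loxa (-7.44 ± 0.14) and pcolcea (-3.31 ± 0.07). Bone and cartilage genes did the same (11 of 15 negative and 0 positive, median -4.01, -3.78 with the floor, camera adjusted p = 4.16e-06), as in tnmd (-7.56 ± 0.19) and alpl (-4.25 ± 0.13). For fusion genes the difference was positive (20 of 36 positive and 6 negative, 20 and 8 adjusted over the list alone, median 1.18, 0.72 with the floor, camera adjusted p = 3.39e-05, adjusted p = 0.119 with an estimated correlation). First came jam2a (2.70 ± 0.08), smyd1b (2.31 ± 0.08), unc45b (2.66 ± 0.12) and chrnd (3.51 ± 0.17). Fusion genes fell in both lines, by less in Mack2 (median -0.51) than in Mack1 (-1.80), as did myog. This did not extend to sarcomere genes, which did not pass as a list (14 of 62 positive and 17 negative, median -0.85, -0.9 with the floor, camera adjusted p = 0.712). Antioxidant genes were on the negative side (23 of 33 negative and 2 positive, 24 and 3 adjusted over the list alone, median -0.40, camera adjusted p = 0.000119), and so were Wnt, Notch, TGF-beta and BMP genes (27 of 48 negative and 12 positive, 28 and 12 adjusted over the list alone, median -0.77, camera adjusted p = 0.00326). Among marker genes that differed were cdkn1a (-1.48 ± 0.08), cdkn2a/b (-0.87 ± 0.13), fabp4a (-5.78 ± 0.69), myod1 (1.94 ± 0.10), myog (2.02 ± 0.34) and plin2 (1.84 ± 0.09). Pax7 (pax7a), the satellite cell factor, went from 5.36 ± 1.04 to 36.1 ± 1.41 CPM in Mack2 and from 0.252 ± 0.0676 to 0.0134 ± 0.0232 CPM in Mack1 (adjusted p = 3.98e-07). Values for pparg (-0.89 ± 0.50) and tert (0.79 ± 0.34) did not pass, with adjusted p of 0.141 and 0.0542. They passed with 1 library left out, for pparg (adjusted p = 0.0457 without p27 proliferation replicate 1 and 0.0256 without Mack2 p2 proliferation replicate 1) and tert (adjusted p = 0.0196 without p27 proliferation replicate 2 and 0.0156 without Mack2 p2 proliferation replicate 2). Of 14706 genes 8305 passed, 4599 positive and 3706 negative. Other scalings moved the median of all genes by -0.10 to -0.11 and put 45.6 to 47.6% of the called genes on the positive side, against 55.4%, so small differences here have no firm sign. Over 13637 genes tested in both lines, the stage changes correlated with r = 0.23 and rho = 0.23. Of them 680 rose and 1349 fell in both, against 584 and 889 for independent lists, and 1218 moved in opposite directions, against 1471. Each line was of its own batch label apart from 1 library, so line and batch cannot be told apart.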

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

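The tests of explanations here and the counts over other splits were made after the results they concern were seen. Differences of differences and their lists were set before.

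Genes of whole chromosomes shifted together between stages, relative to the median of all genes: in Mack1 p77 against p27 the chromosome with rps4x (326 genes, 87.4% of them lower in proliferation) shifted by -0.40, -0.44, -0.42 and -0.39 in proliferation, starvation, reduction and lipid loading, that with serpinh1b by -0.18, -0.17, -0.20 and -0.16 and that with serbp1a by -0.21, -0.12, -0.18 and -0.14. In Mack2 the chromosomes with tgfbi (0.52), rps4x (0.30) and prdx1 (0.28) shifted upward and those with acta1b (-0.37) and ybx1 (-0.43) downward. Against chance, 1000 permutations of the genes gave at most 0.08 to 0.1 in Mack1 and 0.16 in Mack2 (p = 0.001 in each of the 5 stage comparisons, the smallest they can give), and against gene span or expression level, the smallest proliferation shift left after both were regressed out was 0.2 in size. The shift ran along the chromosomes, with 100% of 90 windows of 40 neighbouring genes on the same side in the 2 proliferation comparisons, lay in 16 of 16 late libraries outside all early ones of their state for the leading chromosome of each line, and was not seen in the responses of p27 to the states (permutation p = 0.9, 0.5 and 0.3). A candidate explanation, as a hypothesis, is a change in the number of chromosome copies in the late cultures, which no DNA measurement here can test.

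Mack1 p77 serum starvation replicate 1 stood apart from the other 2 libraries of its group, with an SD of its log2 deviations of 0.53 over 10874 genes, against at most 0.31 in the other Mack1 groups. A mixture with RNA of another group, or a wrong label among these groups, is argued against: the difference to any other group accounted for at most 3.3% of the variance of its deviation. The deviation followed the genomic span of the genes (Spearman's rho 0.44, against -0.25 to 0.28 in libraries of the other groups), with a median of -0.44 in the fifth of genes up to 4.88 kb and 0.22 in the fifth from 25.9 kb. Recovery of RNA that depends on gene length may thus account for part of it, 20.5% of the variance by a smooth curve, and the rest stays open.

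Muscle genes were higher in proliferating p27 than p77 cultures. The 63 sarcomere and fusion genes were chosen from these data by a log2 rise of at least 3 and 20 CPM in serum reduction. As a percentage of the serum reduction level, 60 of the 63 stood lower at p77, with medians of 0.345% at p27 and 0.0275% at p77. Part of the drop may come from the higher p77 level in reduction (sarcomere median 0.52), and some p77 values were 0. A fixed share of differentiated cells would bring about the same percentage for each gene, but the upper quartile was 7.04 times the lower at p27 and 17.1 times at p77, so the genes' own levels in precursors may spread them as well, and a share of such cells in p27 libraries stays open. Cells at an earlier step of differentiation, or a change with immortalization, stay open too and were not tested.

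Other splits into groups of the same sizes were counted in fits of the compared groups alone. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split called 10073 and 8846 genes in starvation, 9715 and 10871 in reduction and 10107 and 10230 in lipid loading against proliferation at p27 and p77, and the highest other split 0. For p77 against p27 in the 4 states it called 4759, 1348, 5791 and 6153, for starvation against reduction 6623 and 2634 and for lipid loading against reduction 9107 and 9400, with 0 again as the highest other. In Mack2 (35 splits) it called 10721, the highest other 0. For the differences of differences 25 splits were drawn. The real one called 1369 for starvation (highest other 1168), 4490 for reduction (1481), 4503 for lipid loading (1948) and 8305 between the lines (6539). Mixed splits pool unlike libraries and widen the spread, so no count excludes chance.

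The response to serum starvation differed between p77 and p27 in 2132 genes, with camera adjusted p of 4.14e-07 for sterol synthesis, 2.24e-30 for fusion and 6.26e-30 for the sarcomere. Positive log2 differences were acta1a 5.13, bmpr1bb (adjusted p = 6.64e-06), chrng 3.44 and myog 3.10. Negative ones were acat2 -0.72, cdkn1a -0.72, hmgcra -1.69 and tm7sf2 -2.08. In each state the muscle differences include the lower start in p77. Sarcomere medians of p77 against p27 were -1.96 in proliferation and 0.36, 0.52 and 1.46 in starvation, reduction and lipid loading. For serum reduction the responses differed in 3555 genes, with camera adjusted p of 2.76e-06 for amino acid synthesis (adjusted p = 0.0848 with an estimated correlation), 8.18e-26 for fusion, 0.00917 for bone and cartilage, 9.17e-25 for the sarcomere and 0.000279 for Wnt, Notch, TGF-beta and BMP signalling. Positive log2 differences were acta1a 6.06, chrng 4.01, myod1 1.14 and myog 3.68, and negative ones cdkn1a -0.69, fabp4a -3.64 and plin2 -0.56. For lipid loading they differed in 3696 genes, with camera adjusted p of 1.03e-14 for cell division (adjusted p = 0.0941 with an estimated correlation), 3.22e-42 for fusion, 3.11e-40 for the sarcomere, 1.32e-11 for smooth muscle, 2.56e-07 for endoplasmic reticulum folding and 2.12e-13 for Wnt, Notch, TGF-beta and BMP signalling. Positive log2 differences were acta1a 4.10, ccnb1 1.89, cdc20 2.00, chrng 4.92, kif20a 1.48, myod1 0.87, myog 4.82 and top2a 1.39, and negative ones cald1a -2.07, csrp1b -2.67, grem2a -3.60, lmod1b -2.38, smad6b -3.68, smad9 -4.76 and tgfb3 -1.62.

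The change between stages differed between Mack2 and Mack1 in 8305 genes, with camera adjusted p of 0.000119 for antioxidants, 8.35e-34 for cell division, 1.07e-32 for the extracellular matrix, 3.39e-05 for fusion (adjusted p = 0.119 with an estimated correlation), 4.16e-06 for bone and cartilage, 5.61e-05 for telomere maintenance and 0.00326 for Wnt, Notch, TGF-beta and BMP signalling. Positive differences were anln 1.84, ccna2 2.38, chrnd 3.51, dkc1 0.96, gar1 1.48, jam2a 2.70, mcm4 2.22, mki67 2.01, myod1 1.94, myog 2.02, nop10 1.43, pax7a (adjusted p = 3.98e-07), plin2 1.84, smyd1b 2.31, unc45b 2.66 and wrap53 1.76. Negative ones were alpl -4.25, cdkn1a -1.48, cdkn2a/b -0.87, col1a1b -3.84, fabp4a -5.78, loxa -7.44, pcolcea -3.31 and tnmd -7.56.

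In Mack2 p180, replicate 4 lay far from the other 3 libraries in 2 of 22 sets of marker gene CPM and totals tested, where chance gives about 1 in 20. For fabp4a, 0.0754 CPM against 0.0499 to 0.052 (a gap of 0.92 of the range) stood for 2 counts against 1 in each other library, the smallest step there is. The other was the total count, 25268306 against 17932211 to 18840112 (a gap of 0.88).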

How the results depend on the processing

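The alternatives here were set in advance, apart from the fit without Mack1 p77 serum starvation replicate 1, the floor in medians of differences of differences and all tests of lipid loading against serum reduction, which were chosen after the result was seen. Of 38 counts of genes that passed, with and without a 2-fold minimum, each stayed within 1.5 times its value with DESeq2, RLE size factors, either other filter, limma-trend on the deposited signal, the later fit and each library left out in turn. Fitting only the groups compared, which applies to 34 Mack1 counts, moved 4. For p77 against p27 in serum starvation it gave 1348 genes against 3345, and 629 against 951 by at least 2-fold. For starvation against reduction at p77 it gave 2634 against 4685, and for the difference between stages in the response to starvation 1369 against 2132. All of these involve the library that stood apart, and the cause was not tested.

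No named gene or list of the text changed direction in any alternative run, nor did its list medians with the floor. With other scalings the percentage of positive genes among those that passed crossed 50 for the difference between the lines (55.4% against 45.6 to 47.6%), the difference between stages in serum reduction (50.9% against 48 to 49.3%) and lipid loading against serum reduction at p27 (49.8% against 49.5 to 50.3%). Of 455 results for named genes 440 passed, and 431 of those passed in every alternative with a value for them. Over 3212 fits of a named gene with 1 library left out, 18 lost the call and 7 gained it. With only the groups compared 3 of 374 lost it and 2 gained it. With no filter 2 of 455 lost it, and by limma-trend 1 gained it. The mean CPM filter left 442 named results with a value. Of 107 list results, 32 lost their call with camera's estimated correlation and 4 gained one with fry, and no list median changed sign under another scaling. Depth limits the genes near the floor: pax7a had 4 to 7 counts per library in proliferating p27 cultures and pparg 3 to 16 in starved ones. The calls lost or gained with 1 library left out were of cdkn1a, cdkn2a/b, fabp4a, myf5, pax7a, plin2, pparg and tert.

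The replicate numbers of the groups are shared in the labels, and no source states that they pair the libraries. Deviations of same-numbered libraries correlated by -0.07 to 0.06 in Mack1 and -0.03 to 0.1 in Mack2, and for 53 of 176 choices of a library and another group the best match had its own number. With the number as a replicate block, each of the 19 counts was lower. The count for serum starvation at p27 was 10003 against 10087, for Mack2 10687 against 10721, and the largest change was from 2132 to 1928, for the difference between stages in the response to starvation. The block changed no call of a named gene and no count of list members by over 1.5 times.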

Other observations

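Lipid loading was also set against serum reduction, both confluent, at each Mack1 stage, comparisons that were chosen after the data were seen. Lipid loading had 20% serum and FGF2, reduction 2.5% serum and no FGF2 listed, so serum, FGF2 and compounds cannot be separated. At p27 the perilipin gene plin2 was 6.64-fold higher in lipid loading, at 827 ± 28.3 CPM (n = 3 each, 2.73 ± 0.13, adjusted p = 1.28e-15), and angptl4 (5.20 ± 0.17) and lpla (1.63 ± 0.11) were higher with it. Genes of muscle differentiation and fusion were lower (32 of 37 lower and 3 higher, median -2.01, camera adjusted p = 6.88e-27). They were led by unc45b (-4.02 ± 0.12), smyd1b (-3.27 ± 0.11) and klhl31 (-3.07 ± 0.11), and myog stood at -2.69 ± 0.18. Sterol synthesis genes were higher (19 of 26 higher and 3 lower, median 0.92, camera adjusted p = 9.42e-08). In front were sqlea (5.07 ± 0.23), acat2 (1.82 ± 0.09) and dhcr7 (1.80 ± 0.09). Heat shock genes were lower (17 of 24 lower and 2 higher, median -1.0, camera adjusted p = 6.94e-10), led by hspb8 (-2.49 ± 0.10), hspa8b (-2.43 ± 0.10) and hspa1b (-3.84 ± 0.17). The Wnt, Notch, TGF-beta and BMP list was higher (31 of 47 higher and 7 lower, median 1.01, 0.90 with genes at their bound, camera adjusted p = 4.24e-05), led by the Wnt target axin2 (1.89 ± 0.09) and the BMP inhibitors smad6b (3.09 ± 0.16), bambia (3.28 ± 0.19) and grem2a (3.49 ± 0.21). In all 8645 genes differed.

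At p77 plin2 stood at 421 ± 17.3 against 48 ± 3.25 CPM (3.13 ± 0.13, adjusted p = 2.35e-16), and the fatty acid carrier gene fabp4a was higher too (3.19 ± 0.66, adjusted p = 0.000169). Fusion genes were lower (31 of 37 lower and 5 higher, median -1.23, camera adjusted p = 3.33e-12), as in unc45b (-2.71 ± 0.11), klhl31 (-2.02 ± 0.10) and smyd1b (-2.08 ± 0.11), and so were heat shock genes (18 of 24 lower and 2 higher, 20 and 2 adjusted over the list alone, median -0.85, camera adjusted p = 1.15e-07). Amino acid synthesis and integrated stress response genes were lower (33 of 44 lower and 6 higher, 34 and 6 adjusted over the list alone, median -1.03, camera adjusted p = 5.91e-13), with the cystathionine synthase cbsa (-1.72 ± 0.07), the tRNA synthetases yars1 (-1.82 ± 0.08) and sars1 (-1.36 ± 0.06) and asns (-1.76 ± 0.08) in front. Of the cyclic AMP targets, sik1 (6.15 ± 0.31), crema (3.66 ± 0.20) and pde4ba (2.43 ± 0.15) were higher and fosab (-2.91 ± 0.14) was lower. In all 8979 genes differed.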
